A study of Mus musculus with 6 samples.

How the data were processed

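Total RNA of mouse retina was sequenced from 3 libraries of C57BL/6J (B6) and 3 of DBA/2J (D2), per the labels with Illumina stranded total RNA libraries, an RNA integrity number of 9.1 to 9.5 and an age of 60 to 100 days. The submitters' processing notes name FastQC, STAR, SAMtools and edgeR and the genome build mm10. The versions of these tools, the read counter, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited raw counts per gene symbol, without normalization, in a count table of 30510 features, of which 6132 had no count in any library. The authors also deposited a table of expression scores, strain means and standard errors on a scaled axis with a mean of 8.00 and an SD of 1.96 over genes in B6. Its false discovery rate, used as an adjusted p-value, is of the authors' comparison of the strains, and the test behind it is not given in the sources used here.

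All 6 count columns were mapped to samples by their titles, and the samples were grouped by the strain in the labels. Feature names were matched to GENCODE release M21 for mm10: 26876 by symbol, 2462 after removal of a transcript suffix and 437 by an older symbol, so that 29775 matched 1 gene. Of the names, 27 had been turned into dates and were not named in the text, and Nnt had no match. Total counts per library are given with the results. At these depths a count of 0 allows up to 0.0686 to 0.102 CPM (3 counts) per library. Ratios with 1 to 3 counts in 1 strain have exact 95% counting intervals, and genes without a count in 1 strain have a lower bound against 3 counts per library, both for counting error only.

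Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were filtered with filterByExpr at its default settings, which left 18588 genes, scaled with TMM factors and fitted with a quasi-likelihood model of strain, D2 minus B6. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and a 2-fold threshold was applied to the fitted fold change. CPM values are scaled by the TMM factors, except shares and levels given per library. Gene lists were tested with camera of limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 31 lists. The correlation was also estimated per list, and fry was run on the same values. Members were counted from the edgeR test, and also adjusted over the list alone. The biological coefficient of variation was 4.40%.

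The tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The lists were rod photoreceptor, cone photoreceptor, bipolar cell, amacrine cell, horizontal cell, retinal ganglion cell, Müller glia, retinal gliosis and stress, microglia, complement, endothelium and pericyte, retinal pigment epithelium, pigmentation, lens, cornea, skeletal muscle, erythrocyte, sex-linked, MHC class I and antigen processing, MHC class II, interferon-stimulated, glaucoma-associated, retinitis pigmentosa and cone dystrophy, photoreceptor ribbon synapse, GABA and glycine receptor, circadian clock, glutathione and oxidative stress, cytosolic ribosomal protein, mitochondrially encoded, immediate early and dissociation response, and known B6 or D2 strain variants. Named genes were drawn from those past the threshold whose libraries did not overlap between strains, with a mean log2 CPM of 1 or more and a symbol that does not mark a clone, pseudogene or accession: the 12 largest fold changes in each direction, and the 6 largest further ones at a mean log2 CPM of 6 or more. In each list, up to 4 members with the lowest adjusted p among those past the threshold and the 2 most abundant members were added, with all tested members of the pigmentation and strain variant lists. Ciliary markers and the genes without a count in 1 strain were chosen after their values, or those of related genes, were seen.

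Alternatives were DESeq2 size factors and upper quartile factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. Removal of Rn18s, Lars2, Rpph1 and the mitochondrial genes was added after seeing the data. The other 9 splits of the 6 libraries into 3 and 3 were tested in the same way. Sequence sharing was the percentage of the 31-base words of a gene's annotated exons that occurred in another gene. Adjacent pairs of changed genes were counted against 10000 permutations of the calls within expression classes. Tables were processed with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. The gene test was tested on simulated data with the same depths and spread. Of 50 genes each changed by 1.2, 1.5, 2 and 4-fold, 26, 40, 47 and 47 were called (52%, 80%, 94% and 94%), and 12 of 18221 unchanged genes were called. Far fewer genes were changed in the simulation than were called in the data. The adjusted p depends on that number, so these shares need not hold for the data. No read-level data were used here, so strain variants within reads were not analysed. Some of the genes that the rule selects are not reported here.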

Results

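Retinal RNA was profiled in 2 inbred mouse strains, C57BL/6J (B6), the strain whose genome is the mouse reference sequence, and DBA/2J (D2), a pigmented strain that carries variants of Gpnmb and Tyrp1 and develops a pigmentary glaucoma with age. Each strain had 3 libraries, made from total RNA of mice aged 60 to 100 days. The B6 and D2 strains are the parents of the BXD family of recombinant inbred mice, and the series was made to add sequencing data to retinal array datasets of that resource. The libraries held 43719666, 41256892 and 31305777 counts in B6 and 29417002, 31863814 and 34478751 counts in D2, over 30510 annotated features. The 10 most abundant features took 9.89% to 12.5% of each library. Levels are given as CPM, counts divided by library size and scaled between libraries, as mean ± SD over n = 3 libraries, and log2 fold changes as D2 minus B6 with their standard errors. The labels do not say whether the libraries of a strain came from separate mice, so p-values measure the spread between these libraries, which may be technical.

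The comparison asked which retinal genes differ in transcript level between the strains. The cone phosphodiesterase subunit Pde6c, the interferon-stimulated gene Oasl2, the complement regulator Cfi and the mitochondrially encoded mt-Nd2 were lower in D2. The GABA-A receptor subunit Gabra2, the rod arrestin Sag, the potassium channel Kcnj10 of Müller glia and the class I histocompatibility gene H2-Q1 were higher in D2. H2-Q1 had a low level in B6 and shares part of its sequence with other genes. Of 18588 tested genes, 5524 changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 2686 higher and 2838 lower in D2. Most of these differences were small: 3856 of the changed genes differed by less than 1.5-fold, and the median absolute log2 fold change of the changed genes was 0.34. At 2-fold or more, 395 genes were higher and 500 lower, and at 4-fold or more 124 were higher and 159 lower. In 7863 genes (42.3%) the 3 libraries of one strain all lay above the 3 of the other, where chance gives 10%, and this held for 5380 of the 5524 changed genes.

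The strain was the main axis of the libraries. The first principal component of the log2 CPM values held 74.3% of the variance and separated the strains, with B6 libraries from -39.3 to -36.4 and D2 libraries from 37.1 to 38.7, and the second held 8.96%. Pearson's r across genes was 0.994 to 0.996 between libraries of a strain and 0.975 to 0.977 between strains (across genes, which are not independent replicates). All 6 libraries held transcripts of the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty, with Eif2s3y at 74.8 to 101 CPM. Reads of both strains were aligned to a reference sequence derived from B6, and the effect of D2 variants on the alignment was not analysed here.

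**Figure D1:**
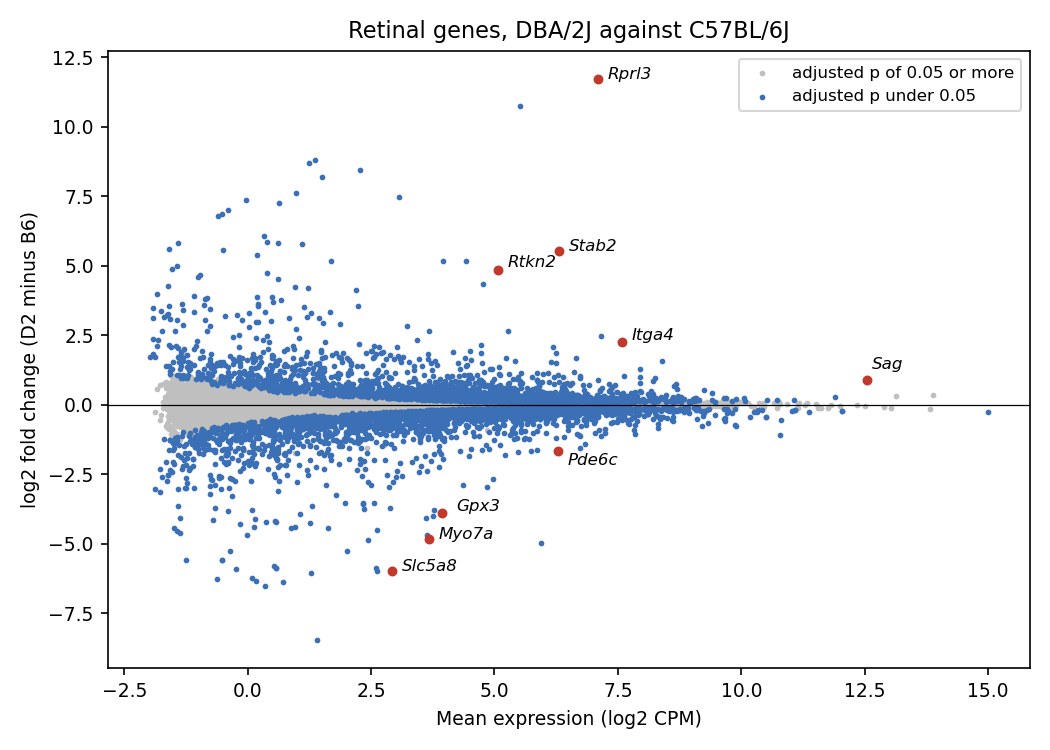
Log2 fold change (D2 minus B6) of each tested gene against its mean expression in log2 CPM over the 6 libraries, with genes at an adjusted p under 0.05 in blue, the others in grey and 9 genes marked in red. The 12 tested genes without a count in 1 strain are not drawn. Rprl3 lies at 11.73 and Slc5a8 at -5.97.

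Among the largest increases in D2 were those of transcripts that were close to the detection limit in B6. Rprl3 (chromosome 8, 3803069 to 3803358), annotated as a ribozyme, rose from 0.0730 ± 0.0575 CPM in B6 to 276 ± 66.2 CPM in D2 (SD, n = 3; log2 fold change 11.73 ± 0.31, adjusted p = 8.65e-13). Its relative Rprl2 (chromosome 3, 22251374 to 22251663) had 6 counts in the 3 B6 libraries and 5026, 300 and 3517 counts in D2 replicates 1, 2 and 3 (log2 fold change 10.74 ± 1.41, adjusted p = 2.99e-05), and limma-voom did not call it (adjusted p = 0.264, range over the alternatives 2.02e-14 to 0.264). The log2 fold change of Rprl2 was 12.40 without B6 replicate 1 and 9.98 without D2 replicate 1, and that of Rprl3 was 12.58 without B6 replicate 1. Sycp1, which encodes a protein of the synaptonemal complex (chromosome 3, 102818499 to 102936100), had 1 count in B6 and 523 in D2, a ratio of 635 with a 95% counting interval of 113 to 25100 that covers counting error only. The B6 count of Sycp1 lay in B6 replicate 3, and its log2 fold change of 8.80 ranged from 8.17 to 10.62 over the alternatives. Serpina3h (chromosome 12, 104247905 to 104253669), annotated as a transcribed unprocessed pseudogene, and the serpin gene Serpina3i (chromosome 12, 104263122 to 104269372) had 3 and 2 counts in B6 and 984 and 580 in D2, ratios of 398 (136 to 1930) and 352 (97.0 to 2910), and 39.8% and 27.3% of their 31-base words also occurred in other genes. Without B6 replicate 1, Serpina3h went from 8.44 to 9.19 on the log2 scale. The 2 B6 counts of Serpina3i lay in B6 replicate 1. Its log2 fold change of 8.18 ranged from 7.62 to 10.67 over the alternatives.

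Among genes with more than 3 counts in every B6 library, the hyaluronan receptor Stab2 (chromosome 10, 86841198 to 87008025) was 46.0-fold higher in D2, at 3.39 ± 0.140 CPM in B6 and 156 ± 78.3 CPM in D2 (SD, n = 3; log2 fold change 5.52 ± 0.34, adjusted p = 7.54e-09). The flavin monooxygenase Fmo1 (chromosome 1, 162829561 to 162866610) was 36.0-fold higher (log2 fold change 5.17 ± 0.28, adjusted p = 1.86e-09) and Adamts13 (chromosome 2, 26973416 to 27009628), the protease that cleaves von Willebrand factor, 35.7-fold higher (log2 fold change 5.16 ± 0.37, adjusted p = 4.92e-08). These 3 genes were all highest in D2 replicate 2 and lowest in D2 replicate 1 by count: D2 replicate 1 held 2566, 840 and 635 counts of Stab2, Fmo1 and Adamts13, and D2 replicate 2 held 7873, 1910 and 1642. Of their 31-base words 1.31%, 7.95% and 4.56% occurred in other genes, and Adamts13 shared most with Fmo1. By contrast Rtkn2 (chromosome 10, 67979570 to 68059740), at 2.27 ± 0.102 CPM in B6 and 66.5 ± 2.57 CPM in D2, had a standard error of 0.06 on a log2 fold change of 4.87 (adjusted p = 3.6e-16). The serine protease Prss41 (chromosome 17, 23836785 to 23844172) was 18.3-fold and the integrin Itgae (chromosome 11, 73090583 to 73147446) 11.8-fold higher.

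At the opposite end, Tnfrsf8 (chromosome 4, 145267137 to 145315164), which encodes the receptor CD30, had 430, 438 and 383 counts in the B6 libraries and 0 in each D2 library, at least 115-fold lower in D2 against a floor of 3 counts per library. The carbohydrate kinase Fggy (chromosome 4, 95557507 to 95926939) was 66.0-fold lower and the monocarboxylate transporter Slc5a8 (chromosome 10, 88885992 to 88929515) 62.7-fold lower, the latter at 13.9 ± 1.31 CPM in B6 and 0.215 ± 0.0889 CPM in D2 (SD, n = 3). Myo7a (chromosome 7, 98051060 to 98119524), an unconventional myosin whose human gene is mutated in Usher syndrome, was 28.0-fold lower, at 23.5 ± 2.39 CPM in B6 and 0.839 ± 0.296 CPM in D2 (log2 fold change -4.81 ± 0.14, adjusted p = 3.23e-12). Eps8l1 (chromosome 7, 4460674 to 4480487) was 25.9-fold lower, but B6 replicate 2 held only 128 counts against 1425 and 1044 in the other B6 libraries, and limma-voom did not call it (adjusted p = 0.121, range over the alternatives 3.77e-13 to 0.121). Also lower were Acoxl (chromosome 2, 127838876 to 128123873; 18.8-fold), the securin gene Pttg1 (chromosome 11, 43420250 to 43426251; 16.6-fold), annexin Anxa1 (chromosome 19, 20373428 to 20390944; 16-fold), the secreted glutathione peroxidase Gpx3 (chromosome 11, 54902453 to 54910377; 15-fold), the histidine decarboxylase Hdc (chromosome 2, 126593667 to 126619299; 13.7-fold), the anion exchanger Slc26a4 (chromosome 12, 31519827 to 31559969; 13.1-fold) and Col6a4 (chromosome 9, 105989454 to 106096783; 12.5-fold). Of 10 tested markers of ciliary epithelium, a list written after the fall of Gpx3 and Slc26a4 was seen, 9 also fell in D2, with a median log2 fold change over the 10 of -0.702 ± 0.216 (bootstrap standard error). The 9 ranged from -1.62 ± 0.42 for Otx1 to -0.25 ± 0.04 for Col9a1, and Aqp1, the most abundant, did not pass (-0.06 ± 0.04, adjusted p = 0.364).

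Of the more abundant genes, the largest differences not already given were in Sfi1 (chromosome 11, 3131850 to 3193463), a centrosomal gene, 5.58-fold higher at 43.5 ± 3.34 CPM in B6 and 242 ± 6.59 CPM in D2, and in Itga4 (chromosome 2, 79255426 to 79333123), integrin alpha 4, 4.76-fold higher at 66.6 ± 2.54 CPM in B6 and 317 ± 16 CPM in D2 (SD, n = 3). Cerkl (chromosome 2, 79330543 to 79456785), a retinitis pigmentosa gene that overlaps Itga4 on the opposite strand, was 4.28-fold higher. The strand setting of the counting is not given in the sources used here, so counts in the overlap could not be assigned to either gene. The histone H4 genes Hist1h4f (chromosome 13, 23551258 to 23551648) and Hist1h4a (chromosome 13, 23760692 to 23761230) were 3.68-fold and 3.22-fold higher, and 53.2% and 47.9% of their 31-base words occurred in other genes, so their separate levels are uncertain. Of the 862 genes with sequence that changed by 2-fold or more, 248 (28.8%) shared 20% or more of their words with other genes. The share among all tested genes was not computed, so it is not known whether large differences go with shared sequence.

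In the cone list, which holds phototransduction and cone identity genes, 10 of 13 genes fell in D2 and 0 rose (camera adjusted p = 3.42e-06, adjusted p = 0.236 with an estimated correlation, range over the alternatives 7.93e-07 to 0.236). Of the 13, 10 passed when adjusted over the list alone. Of the cone phosphodiesterase subunits, Pde6c (chromosome 19, 38132781 to 38183958) fell from 118 ± 0.626 CPM in B6 to 37.1 ± 0.889 CPM in D2 (SD, n = 3; log2 fold change -1.67 ± 0.04, adjusted p = 1.14e-13). Pde6h (chromosome 6, 136923832 to 136968865) fell from 165 ± 7.26 CPM in B6 to 62.9 ± 2.14 CPM in D2 (log2 fold change -1.39 ± 0.04, adjusted p = 2.82e-12). The cyclic nucleotide-gated channel subunit Cnga3 fell 1.71-fold (log2 fold change -0.77 ± 0.07, adjusted p = 1.37e-06) and the thyroid hormone receptor Thrb 1.35-fold (log2 fold change -0.43 ± 0.04, adjusted p = 4.15e-07). The short-wavelength opsin Opn1sw did not pass the test (515 ± 14.3 CPM in B6 and 527 ± 64.8 CPM in D2; log2 fold change 0.03 ± 0.06, adjusted p = 0.753), nor did Gnb3 (-0.06 ± 0.04 log2, adjusted p = 0.231).

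**Figure D2:**
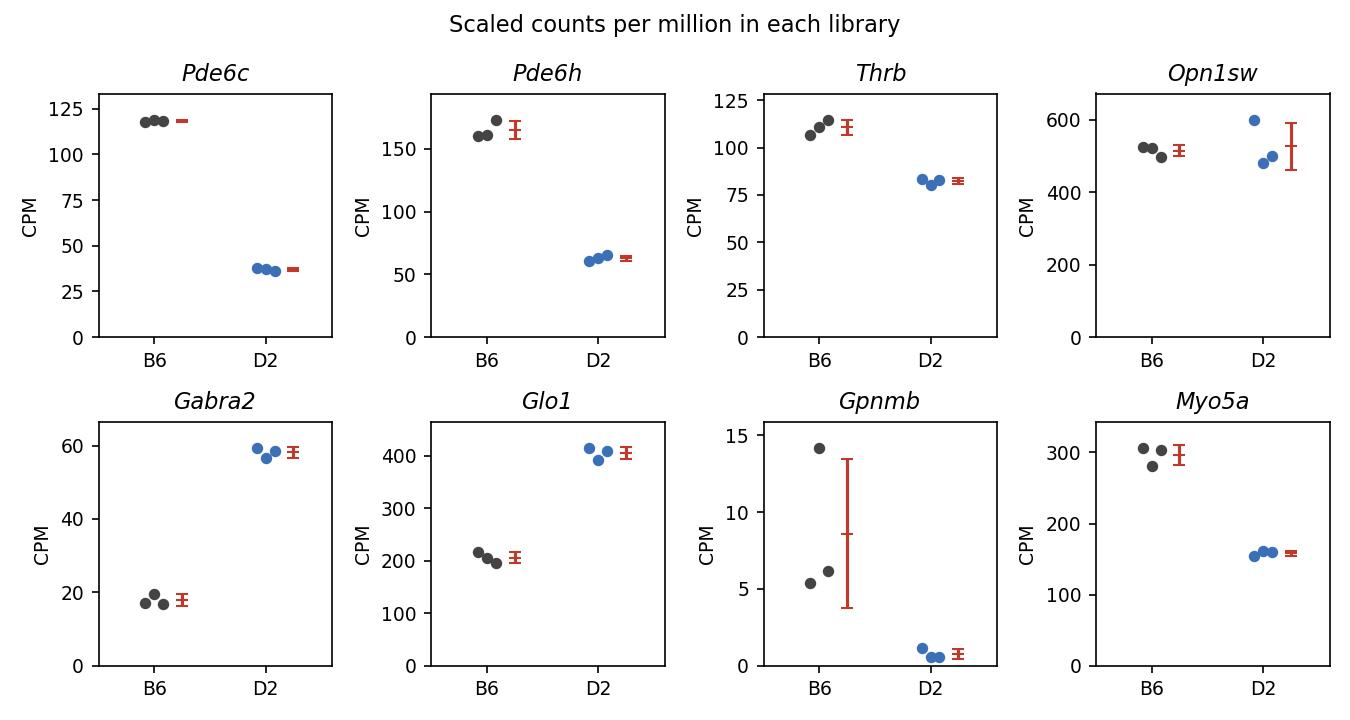
Scaled CPM of 8 genes in each of the 6 libraries (points, B6 grey and D2 blue), with the mean and SD of n = 3 libraries in red, each gene on its own linear axis from 0. Pde6c, Pde6h, Thrb, Gpnmb and Myo5a lie lower in all 3 D2 libraries, Gabra2 and Glo1 lie higher, and Opn1sw overlaps between strains at 515 ± 14.3 and 527 ± 64.8 CPM.

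Rod genes showed no common shift: of 18, 4 rose, 1 fell and 13 did not pass (camera adjusted p = 0.377). Of the 18, 5 passed when adjusted over the list alone. Sag, the rod arrestin (chromosome 1, 87803680 to 87845158), rose from 4244 ± 115 CPM in B6 to 7798 ± 494 CPM in D2 (SD, n = 3; log2 fold change 0.88 ± 0.06, adjusted p = 2.17e-08), and Rp1, a photoreceptor microtubule gene, rose 1.21-fold (log2 fold change 0.27 ± 0.05, adjusted p = 0.000566). The rod transducin Gnat1 had -0.10 ± 0.06 log2 (adjusted p = 0.208) and passed by DESeq2 (adjusted p = 0.0245, range over the alternatives 0.0245 to 0.467), without overlap between the strains' libraries. Among 23 genes of inherited retinal degeneration, 5 rose and 7 fell (camera adjusted p = 0.758, with a median log2 fold change of 0.03, a mean of -0.21 and a downward test). Of the 23, 12 passed when adjusted over the list alone. Besides Myo7a, the ciliary scaffold Rpgrip1 (1.62-fold; log2 fold change -0.69 ± 0.05, adjusted p = 1.01e-07) and the actin-bundling Fscn2 (1.52-fold) fell, and the interphotoreceptor matrix gene Impg1 rose (1.32-fold; log2 fold change 0.40 ± 0.04, adjusted p = 6.31e-07). In the photoreceptor ribbon synapse list 2 of 16 genes rose and 2 fell (camera adjusted p = 0.855, with a median of 0.01, a mean of -0.01 and an upward test). Of the 16, 4 passed when adjusted over the list alone. The scaffold Pclo fell (log2 fold change -0.30 ± 0.07, adjusted p = 0.0028). Vamp2 rose (log2 fold change 0.15 ± 0.04, adjusted p = 0.00446). The vesicular glutamate transporter Slc17a7 stood at 0.05 ± 0.04 log2 (adjusted p = 0.395).

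In the inner retina, 8 of 18 ganglion cell genes fell and 1, Sncg, rose (camera adjusted p = 0.0209, adjusted p = 0.783 with an estimated correlation, range over the alternatives 0.000214 to 0.783). Of the 18, 9 passed when adjusted over the list alone. The neurofilament gene Nefm fell 1.43-fold (log2 fold change -0.52 ± 0.05, adjusted p = 1.14e-06), Nefl 1.37-fold (log2 fold change -0.46 ± 0.06, adjusted p = 5.33e-05, with 32.2% of its words shared with Nefm) and Nefh 1.41-fold (log2 fold change -0.49 ± 0.07, adjusted p = 0.000119). Nefm and Nefl overlap on opposite strands of chromosome 14. Counts in the overlap could not be assigned to either gene, so their falls may not be independent. Thy1 fell 1.2-fold. The list lost its call without B6 replicate 1 (adjusted p = 0.0986), B6 replicate 2 (0.0903) or D2 replicate 2 (0.0615). Of 14 bipolar cell genes 3 rose and 1 fell (camera adjusted p = 0.299). Of the 14, 5 passed when adjusted over the list alone. The calcium-binding Cabp5 rose 1.46-fold (log2 fold change 0.55 ± 0.05, adjusted p = 4.49e-07). The ON bipolar channel Trpm1 fell 1.27-fold (log2 fold change -0.34 ± 0.04, adjusted p = 1.59e-05). Of 15 amacrine cell genes 3 rose and 2 fell (camera adjusted p = 0.409). Of the 15, 5 passed when adjusted over the list alone. The GABA-synthesising enzyme Gad2 rose (log2 fold change 0.47 ± 0.05, adjusted p = 2.79e-06), as did tyrosine hydroxylase Th (log2 fold change 0.55 ± 0.14, adjusted p = 0.0064). Of 6 horizontal cell genes 1 rose and 3 fell (camera adjusted p = 0.175), with Prox1 higher (0.29 ± 0.03 log2) and the gap junction gene Gja10 lower (-0.66 ± 0.16 log2). Of the 6, 4 passed when adjusted over the list alone.

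Of 19 GABA and glycine receptor subunits, 3 rose and 4 fell (camera adjusted p = 0.855, with a median of -0.01, a mean of 0.07 and a downward test). Of the 19, 7 passed when adjusted over the list alone. Gabra2 (chromosome 5, 70957597 to 71095849) rose 3.25-fold, from 17.9 ± 1.57 CPM in B6 to 58.2 ± 1.46 CPM in D2 (SD, n = 3; log2 fold change 1.70 ± 0.06, adjusted p = 8.09e-12). Gabra3 fell 1.24-fold (log2 fold change -0.31 ± 0.06, adjusted p = 0.00126), Gabrr2 fell 1.16-fold and the glycine receptor subunit Glra3 rose 1.21-fold.

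Among 14 Müller glia genes 1 rose and 6 fell (camera adjusted p = 0.138). Of the 14, 7 passed when adjusted over the list alone. The inward rectifier Kcnj10 (chromosome 1, 172341210 to 172374085) rose 2.09-fold, from 22.6 ± 0.525 CPM in B6 to 47.3 ± 1.19 CPM in D2 (SD, n = 3; log2 fold change 1.06 ± 0.04, adjusted p = 1.04e-10). Apoe fell 1.5-fold (log2 fold change -0.59 ± 0.05, adjusted p = 1.94e-07) and clusterin, Clu, fell 1.43-fold (log2 fold change -0.52 ± 0.04, adjusted p = 9.48e-08). In the gliosis and stress list 8 of 14 genes fell and 0 rose (camera adjusted p = 0.00527, adjusted p = 0.518 with an estimated correlation, range over the alternatives 0.000214 to 0.518), among them Fgf2 (log2 fold change -0.84 ± 0.07, adjusted p = 3.59e-07), ceruloplasmin, Cp (log2 fold change -0.50 ± 0.05, adjusted p = 2.35e-06), and Lcn2 (log2 fold change -0.84 ± 0.17, adjusted p = 0.00157). Of the 14, 9 passed when adjusted over the list alone. Gfap was at 0.39 ± 0.18 log2 (adjusted p = 0.127) and Stat3 at -0.03 ± 0.04 (adjusted p = 0.678).

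Of 15 microglia genes 7 fell and 0 rose (camera adjusted p = 0.00397, adjusted p = 0.299 with an estimated correlation, range over the alternatives 0.00138 to 0.299). Of the 15, 8 passed when adjusted over the list alone. C1qc fell 2.45-fold (log2 fold change -1.29 ± 0.14, adjusted p = 3.48e-06) and C1qb 2.62-fold (log2 fold change -1.39 ± 0.18, adjusted p = 2.3e-05), whereas the receptor Csf1r, at 14.6 ± 0.310 CPM in B6 and 13.7 ± 0.685 CPM in D2 (SD, n = 3), had -0.09 ± 0.06 log2 (adjusted p = 0.281). In the complement list, which shares the 3 C1q genes with the microglia list, 9 of 14 genes fell and 1 rose (camera adjusted p = 0.00445, adjusted p = 0.46 with an estimated correlation, range over the alternatives 0.000941 to 0.46). Of the 14, 10 passed when adjusted over the list alone. C1qb (136880129 to 136886187) and C1qc (136889804 to 136893065) lie close together on chromosome 4, so their falls may not be independent. Complement factor I, Cfi (chromosome 3, 129835884 to 129875332), fell 6.01-fold, at 2.26 ± 0.248 CPM in B6 and 0.371 ± 0.162 CPM in D2, and the C1 inhibitor Serping1 fell 2.82-fold (log2 fold change -1.50 ± 0.16, adjusted p = 2.96e-06). Cd59a, a regulator of the membrane attack complex, rose 1.34-fold (log2 fold change 0.43 ± 0.05, adjusted p = 4.67e-06).

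Interferon-stimulated genes were lower in D2: 16 of 20 fell and 1, Xaf1, rose (camera adjusted p = 8.09e-07, adjusted p = 0.236 with an estimated correlation, range over the alternatives 1.38e-07 to 0.236). Of the 20, 19 passed when adjusted over the list alone. Oasl2 (chromosome 5, 114896936 to 114912234) fell 4.08-fold, from 7.79 ± 0.440 CPM in B6 to 1.91 ± 0.147 CPM in D2 (SD, n = 3; log2 fold change -2.03 ± 0.11, adjusted p = 2.99e-09), the RNA sensor Ifih1 fell 2.34-fold (log2 fold change -1.23 ± 0.10, adjusted p = 2.75e-07), Ifit3 1.90-fold (log2 fold change -0.92 ± 0.08, adjusted p = 5.31e-07) and Bst2 4.25-fold (log2 fold change -2.09 ± 0.24, adjusted p = 8.62e-06). Of the words of Ifit3, 61.8% also occurred in Ifit3b. The transducer Stat2 had 0.05 ± 0.05 log2 (adjusted p = 0.53).

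Histocompatibility genes differed in both directions. Of 19 class I and antigen processing genes 7 rose and 6 fell (camera adjusted p = 0.855, with a median of -0.08, a mean of 0.35 and an upward test). Of the 19, 13 passed when adjusted over the list alone. H2-Q1 (chromosome 17, 35320405 to 35325099) rose 8.64-fold, H2-Q2 8.12-fold, H2-Q6 4.59-fold and H2-Q4 3.14-fold, and these genes shared 24.1% to 53.0% of their words with other genes. H2-Q1 and H2-Q2 were low in B6, at 0.571 ± 0.140 and 0.307 ± 0.0887 CPM. The class I gene H2-L, also on the list, was not among the counted features. The separate levels of the H2-Q genes are therefore uncertain. Of 7 class II genes 1 rose and 4 fell (camera adjusted p = 0.0209, adjusted p = 0.484 with an estimated correlation, range over the alternatives 0.00339 to 0.484). Of the 7, 5 passed when adjusted over the list alone. The invariant chain Cd74 fell 3.56-fold, at 1.93 ± 0.195 CPM in B6 and 0.540 ± 0.0177 CPM in D2 (SD, n = 3; log2 fold change -1.83 ± 0.20, adjusted p = 5.75e-06), H2-DMb1 fell 8.88-fold and H2-Eb1 3.83-fold, all at low levels, while H2-Ab1 rose 2.34-fold (log2 fold change 1.23 ± 0.16, adjusted p = 3.32e-05). The class II call was lost without B6 replicate 2 (adjusted p = 0.0526), with no filter on low counts (0.153) and with a filter of 1 CPM in 3 libraries (0.423).

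Of 14 endothelial and pericyte genes 1 rose and 3 fell (camera adjusted p = 0.119, fry adjusted p = 0.00147 downward). Of the 14, 5 passed when adjusted over the list alone. Von Willebrand factor, Vwf, fell 2.35-fold, from 6.75 ± 0.197 CPM in B6 to 2.87 ± 0.164 CPM in D2 (SD, n = 3; log2 fold change -1.23 ± 0.10, adjusted p = 3.11e-07). The receptor Flt1 fell 1.18-fold, while the pericyte gene Rgs5 had 0.00 ± 0.04 log2 (adjusted p = 0.964). Of 5 erythrocyte genes 4 rose, while the list as a whole did not pass by camera or fry (camera adjusted p = 0.0915, fry adjusted p = 0.11). Of the 5, 5 passed when adjusted over the list alone. Hba-a1 rose 2.16-fold, at 25.1 ± 5.29 CPM in B6 and 54.2 ± 23.5 CPM in D2, with its highest level, 81.3 CPM, in D2 replicate 1. Hbb-bs rose 1.85-fold, with 54.4% to 92.6% of the words of the 4 globin genes shared with other genes. The erythrocyte list passed without D2 replicate 3 (adjusted p = 0.0386, range over the alternatives 0.0386 to 0.684). Hba-a2 lost its call without B6 replicate 1 (0.60 log2) or D2 replicate 1 (0.35 log2). DESeq2 did not call Hba-a2, Hbb-bs or Hbb-bt (adjusted p = 0.182, 0.0948 and 0.101, the highest over the alternatives, against lowest values of 0.000366, 1.23e-05 and 5.18e-05). In the sex-linked list Eif2s3y rose (log2 fold change 0.22 ± 0.05, adjusted p = 0.00238) and the other 3 tested genes did not pass (camera adjusted p = 0.313). Of the 4, 3 passed when adjusted over the list alone. Of these, Ddx3y passed without B6 replicate 1 (0.20 log2) and with no filter on low counts (adjusted p = 0.0331, range over the alternatives 0.00446 to 0.341).

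Of 13 pigmentation genes 1 rose and 3 fell (camera adjusted p = 0.299). Of the 13, 4 passed when adjusted over the list alone. Gpnmb (chromosome 6, 49036546 to 49070929), whose D2 allele carries a premature stop codon, fell 11.8-fold, from 8.58 ± 4.85 CPM in B6 to 0.748 ± 0.343 CPM in D2 (SD, n = 3; log2 fold change -3.56 ± 0.39, adjusted p = 5.32e-06). The dilute gene Myo5a (chromosome 9, 75071015 to 75223688), for which D2 carries a retroviral insertion, fell 1.88-fold (log2 fold change -0.91 ± 0.04, adjusted p = 2.08e-10). Rab38 fell 1.79-fold. Rab27a was higher (log2 fold change 0.27 ± 0.08, adjusted p = 0.0153) and lost its call without B6 replicate 1 (0.22 log2) or D2 replicate 2 (0.22 log2). The melanosomal genes varied widely within a strain: Tyrp1 stood at 7.81 ± 5.08 CPM in B6 and 7.90 ± 8.81 CPM in D2 (log2 fold change -0.04 ± 0.56, adjusted p = 0.964), with 520 counts in D2 replicate 1 against 117 and 72 in the other D2 libraries, and 568 in B6 replicate 2 against 201 and 159 in the other B6 libraries. Without D2 replicate 1, Tyrp1 (-1.48 log2), Dct (-1.76), Pmel (-2.11) and Mlana (-2.38) passed the test. Without B6 replicate 2 the same 4 genes stood at 0.66, 0.12, 0.25 and 0.34 log2 and did not pass, so that the direction depended on the library left out. The remaining members, Slc24a5, Oca2, Tyr, Slc45a2 and Mlph, had log2 fold changes from -0.20 to 0.15 and did not pass. Over the alternatives the values ranged from -0.82 to 0.37 for Tyr, -0.74 to 0.18 for Oca2, -0.53 to 0.60 for Slc45a2 and -0.21 to 0.49 for Mlph, with both signs for each, so no direction is given for them.

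Transcripts of tissues next to the retina were present. Of 10 pigment epithelium genes 1 rose and 2 fell (camera adjusted p = 0.492), with the photopigment-like Rrh lower (log2 fold change -0.26 ± 0.06, adjusted p = 0.00432) and Ttr, at 37.4 ± 17.9 CPM in B6 and 19.9 ± 13.7 CPM in D2 (SD, n = 3), not passing (adjusted p = 0.0861). Of the 10, 3 passed when adjusted over the list alone. Ttr passed without B6 replicate 1 (-1.21 log2) or D2 replicate 2 (-1.61 log2), with replicate as a block (adjusted p = 0.0364), and with no filter on low counts (adjusted p = 0.00817, range over the alternatives 0.00288 to 0.439). Of 15 lens genes 4 fell (camera adjusted p = 0.299), and the list passed without B6 replicate 1 (adjusted p = 6.96e-08, range over the alternatives 6.96e-08 to 0.911). Of the 15, 3 passed when adjusted over the list alone. The heat-shock crystallin Cryab fell 1.27-fold (log2 fold change -0.35 ± 0.07, adjusted p = 0.00201). The gamma crystallins Crygb, Crygc and Crygd fell by 2.77, 2.51 and 2.15 on the log2 scale, with calls that depended on single libraries, and neither DESeq2 nor limma-voom called them. Each lost its call without B6 replicate 2 (-2.36, -2.20 and -1.75 log2) or D2 replicate 2 (-2.60, -2.51 and -1.88 log2). Crygc also lost it without B6 replicate 3 (-1.98) or D2 replicate 3 (-2.46), and Crygd without B6 replicate 3 (-1.74) or D2 replicate 1 (-1.89). Without B6 replicate 1 the 3 genes stood at -3.37, -3.11 and -2.76 log2, and Crygd stood at -2.98 without D2 replicate 3. For these 3 genes, as for Acta1, the libraries of the strains overlapped. Of 6 corneal genes 1, Krt12, fell (camera adjusted p = 0.855) and lost its call without B6 replicate 3 (-0.82 log2) or D2 replicate 1 (-0.76 log2). Of the 6, 1 passed when adjusted over the list alone. Of 3 tested skeletal muscle genes 1, Acta1, rose (camera adjusted p = 0.583), and its call was lost without any 1 of B6 replicates 1 and 2 and D2 replicates 1 and 3 (0.57, 0.41, 0.54 and 0.55 log2), and by DESeq2 (adjusted p = 0.0939, range over the alternatives 0.00759 to 0.192). Of the 3, 1 passed when adjusted over the list alone.

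Among 22 genes associated with glaucoma or intraocular pressure, 6 rose and 10 fell (camera adjusted p = 0.313). Of the 22, 16 passed when adjusted over the list alone. The latent TGF-beta binding protein Ltbp2 (chromosome 12, 84783212 to 84876532) fell 5.76-fold, from 11.6 ± 1.45 CPM in B6 to 2.06 ± 1.33 CPM in D2 (SD, n = 3; log2 fold change -2.53 ± 0.26, adjusted p = 2.78e-06), Cyp1b1 fell 1.54-fold (log2 fold change -0.62 ± 0.09, adjusted p = 5.82e-05) and Abca1 1.25-fold (log2 fold change -0.32 ± 0.05, adjusted p = 0.000158). Gas7 rose 1.23-fold (log2 fold change 0.30 ± 0.05, adjusted p = 0.000122). Ltbp2 fell beside the ciliary epithelium markers, of which 9 of 10 fell. Of 11 tested genes on the list of known B6 or D2 variants 3 rose and 5 fell (camera adjusted p = 0.375). Of the 11, 8 passed when adjusted over the list alone. Besides Gabra2, the methylglyoxal-detoxifying enzyme Glo1 (chromosome 17, 30584936 to 30626871) rose 1.97-fold, from 206 ± 10.0 CPM in B6 to 406 ± 12 CPM in D2 (log2 fold change 0.98 ± 0.04, adjusted p = 1.27e-10), and the haem synthesis enzyme Alad (chromosome 4, 62509169 to 62519918) rose 2.72-fold (log2 fold change 1.44 ± 0.06, adjusted p = 1.92e-10). Entpd4 (chromosome 14, 69337174 to 69367270) fell 2.02-fold (log2 fold change -1.02 ± 0.03, adjusted p = 9.93e-12), with all of its words shared with other genes, among them Entpd4b, and the mitochondrial transhydrogenase Nnt fell 1.39-fold (log2 fold change -0.48 ± 0.07, adjusted p = 0.000124). For Nnt, as for other genes, the effect of D2 variants on alignment to the B6-derived reference was not analysed. Its lower D2 count may therefore not reflect transcript level, and it does not show which strain carries a variant of Nnt. Ahr (0.05 ± 0.04 log2, adjusted p = 0.45) did not pass.

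Of 15 mitochondrially encoded genes 13 fell and 0 rose (camera adjusted p = 7.37e-08, adjusted p = 0.484 with an estimated correlation, range over the alternatives 7.37e-09 to 0.484). Of the 15, 13 passed when adjusted over the list alone. mt-Nd2 fell 1.77-fold, from 403 ± 7.46 CPM in B6 to 228 ± 10.6 CPM in D2 (SD, n = 3; log2 fold change -0.82 ± 0.04, adjusted p = 5.25e-10), mt-Nd3 1.71-fold (log2 fold change -0.77 ± 0.05, adjusted p = 9.06e-09) and mt-Cytb 1.57-fold (log2 fold change -0.65 ± 0.04, adjusted p = 7.5e-09), whereas mt-Co1, at 7763 ± 158 CPM in B6 and 7441 ± 396 CPM in D2, had -0.06 ± 0.06 log2 (adjusted p = 0.469). The ribosomal RNA mt-Rnr2 did not pass (adjusted p = 0.239) except without D2 replicate 1 (-0.25 log2). The mitochondrial transcripts together took 3.89 ± 0.173% of counts in B6 and 3.35 ± 0.187% in D2 (SD, n = 3). Nuclear copies share 98.1% of the words of mt-Nd3 and 13.5% of those of mt-Nd2, and 63.9% of those of mt-Co1 occur in other genes.

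Of 16 genes listed for the immediate early and dissociation response, 10 fell in D2 and 0 rose (camera adjusted p = 0.0002, adjusted p = 0.426 with an estimated correlation, range over the alternatives 6.08e-05 to 0.426). Of the 16, 11 passed when adjusted over the list alone. Egr1 fell 4.08-fold, from 20.3 ± 2.52 CPM in B6 to 5.08 ± 2.17 CPM in D2 (SD, n = 3; log2 fold change -2.03 ± 0.19, adjusted p = 7.25e-07), Fos 3.05-fold (log2 fold change -1.61 ± 0.10, adjusted p = 1.13e-08) and Nr4a1 2.30-fold (log2 fold change -1.20 ± 0.11, adjusted p = 5.37e-07). Hspa1a fell 1.34-fold, with 70.1% of its words shared, mainly with Hspa1b. All tissue was taken in the same part of the morning, per the labels' protocols, and of 19 clock genes 4 rose and 6 fell (camera adjusted p = 0.855). Of the 19, 12 passed when adjusted over the list alone. Bhlhe41 rose 1.29-fold (log2 fold change 0.36 ± 0.04, adjusted p = 2.04e-06). Per2 fell 1.28-fold (log2 fold change -0.35 ± 0.05, adjusted p = 0.000112). Nr1d2 had 0.09 ± 0.04 log2 (adjusted p = 0.126) and passed without B6 replicate 1 (0.14 log2).

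Of 24 genes of glutathione and oxidative stress metabolism 2 rose and 7 fell (camera adjusted p = 0.375). Of the 24, 9 passed when adjusted over the list alone. Beside Gpx3 and Glo1, the glutathione transferase Gsta4 rose 1.64-fold (log2 fold change 0.71 ± 0.04, adjusted p = 7.86e-09). Gstm1 fell 1.89-fold (log2 fold change -0.91 ± 0.10, adjusted p = 7.21e-06). Gpx4 had -0.06 ± 0.04 log2 (adjusted p = 0.339). Of 49 cytosolic ribosomal protein genes 9 rose and 6 fell (camera adjusted p = 0.299), and the list passed without D2 replicate 2 (adjusted p = 0.0445, range over the alternatives 0.0445 to 0.911). Of the 49, 16 passed when adjusted over the list alone. Rps23 rose 1.83-fold (log2 fold change 0.87 ± 0.04, adjusted p = 1.7e-10). Rplp0 fell 1.48-fold (log2 fold change -0.57 ± 0.04, adjusted p = 3.57e-08). Of the words of Rps23 and Rplp0, 38.6% and 42.8% also occurred in other genes. Over all 31 lists, 9 passed by camera with a preset correlation, each lower in D2, and 0 passed with an estimated correlation, where 3 lists had an unadjusted p under 0.05. In the other 9 splits of the 6 libraries into 3 and 3, camera with the preset correlation called 1 to 9 lists. By fry 15 lists passed, 3 upward and 12 downward, 7 of them among the 9, without the ganglion cell and gliosis lists. The lists that passed by fry and not by camera were, upward, MHC class I (adjusted p = 0.00572), amacrine cell (0.00669) and sex-linked (0.0219). Downward they were endothelium and pericyte (0.00147), horizontal cell (0.00339), glaucoma-associated (0.00925), strain variants (0.0219) and retinitis pigmentosa and cone dystrophy (0.0447).

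**Figure D3:**
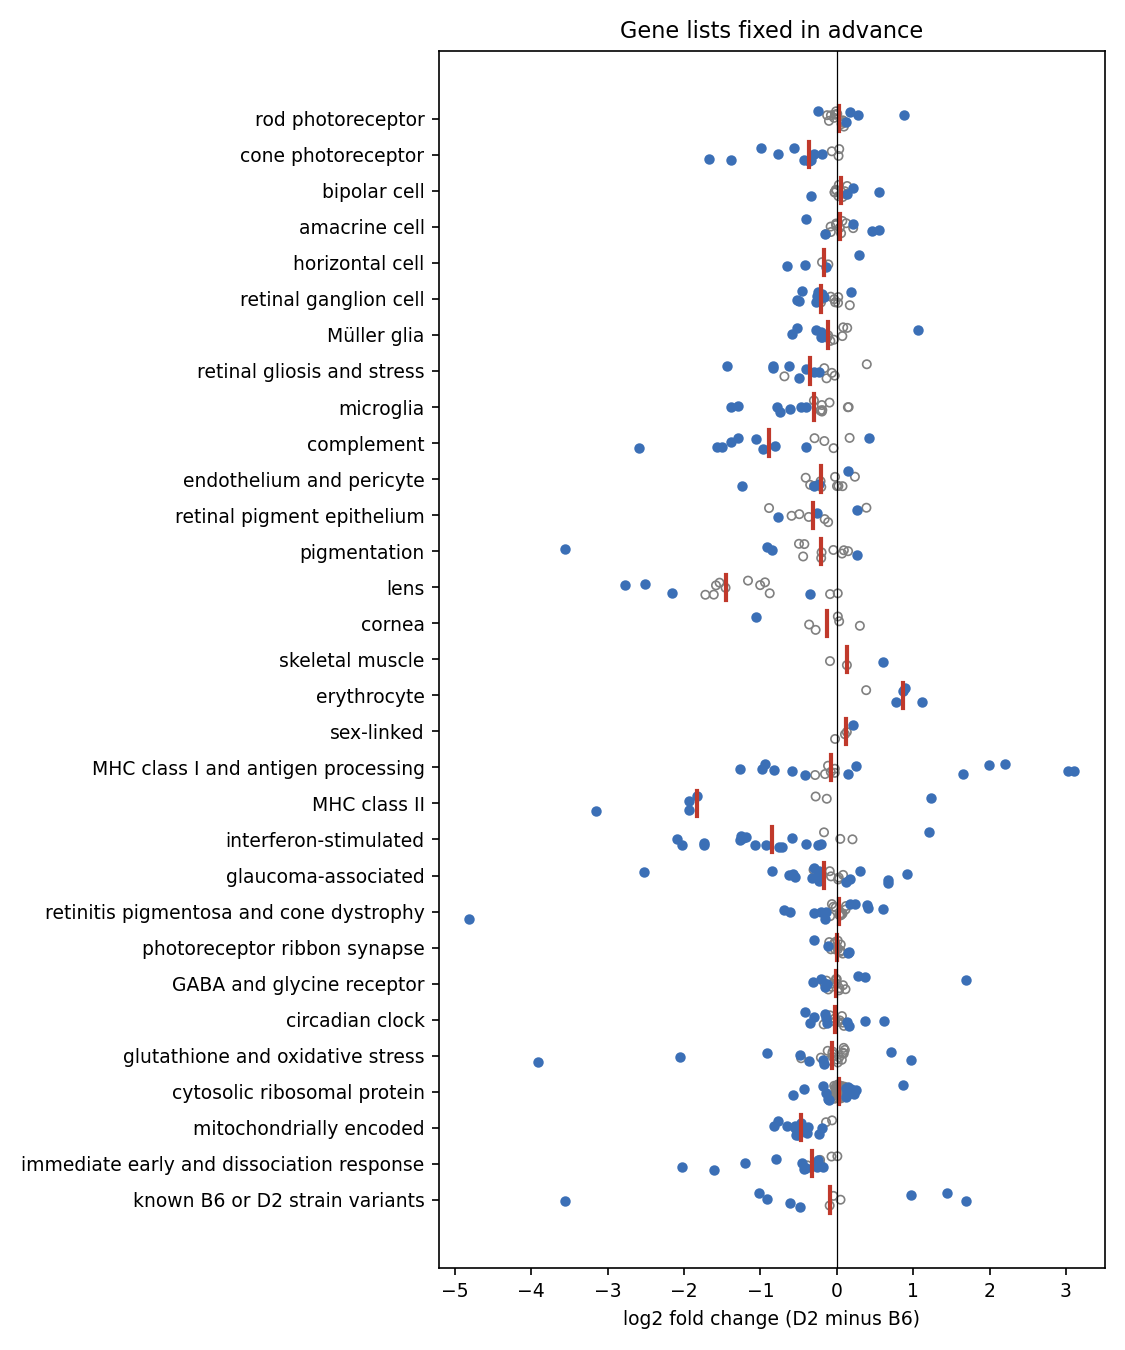
Log2 fold change (D2 minus B6) of every tested member of the 31 gene lists, with members at an adjusted p under 0.05 as filled blue points, the others as open grey points and the list median as a red bar (points are spread vertically for legibility). The medians of the mitochondrially encoded, cone photoreceptor and interferon-stimulated lists lie at -0.47, -0.37 and -0.84.

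The authors' deposited table gives a scaled mean per strain and a false discovery rate for 18100 genes, of which 18056 matched a tested gene. By the authors' false discovery rate, 7404 genes lay under 0.05 and 1665 were marked as differentially expressed, 697 higher and 968 lower in D2. The marked genes had a false discovery rate of at most 0.000996 and an absolute scaled difference of at least 0.316, so the mark was stricter than 0.05. Of the matched genes under 0.05 by the authors' false discovery rate, 73.2% passed here. Of the 1655 marked genes that matched, 1633 (98.7%) also passed edgeR's quasi-likelihood test on the counts, and 1642 had the same sign. Across matched genes, the scaled difference in the authors' deposited table and the log2 fold change from the counts had Pearson's r = 0.970, with a slope of 0.71 scaled units per log2 unit. At thresholds of 0.05, 5408 genes passed in both, 1977 only in the authors' deposited table and 41 only here. The standard errors in that table were a median of 6.96 (B6) and 7.20 (D2) times those of the log2 CPM values, and their scale is not given in the sources used here.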

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

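The removal of rRNA-like and mitochondrial genes was chosen after seeing the data, and the other alternatives before. The count of genes changed between strains, 5524, lay between 4453 (DESeq2 Wald test) and 5774 (no filter beyond 1 count), and between 4502 and 5171 when 1 library was left out. The genes changed between strains by 2-fold or more, 895, lay between 602 (1 CPM in 3 libraries) and 1136 (no filter), with fewer or more genes tested, and between 881 and 972 when 1 library was left out. With the replicate block, 5093 genes changed, 903 of them by 2-fold or more. The gene lists changed between strains, 9 by camera, numbered 0 with the correlation estimated per list, where 3 lists had an unadjusted p under 0.05, and 15 by fry, which tests whether a list moves one way and not whether it differs from other genes. Without 1 library, 7 to 10 lists passed. The agreement of the deposited normalized table with the counts, as a correlation across genes, was 0.9701 by Pearson, 0.9592 by Spearman and 0.9555 to 0.9657 without 1 library, each of which leaves fewer libraries behind 1 of the values compared. The cause of the lower Spearman value was not tested. Of 190 named genes 147 passed, 122 of them under every alternative in which they were tested, and 0 changed direction while called. Some alternatives left out a few of the named genes. Scaling alternatives moved the median of all genes by -0.00392 to -0.00108 on the log2 scale.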

Other observations

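Tests of other splits, of cone number, of nuclear copies and a common factor for mitochondrial genes, and of the pigment epithelium were chosen after the result was seen, as were the genes named here. Of the tested genes, 12 had no count in 1 strain, and all 12 passed edgeR's test. The filter kept such genes only with counts in all 3 libraries of the other strain, so their passing was nearly given. The carboxylesterase Ces1a had 0 counts in B6 and 369 in D2, at least 48.6-fold higher, and the meiotic gene Ccnb1ip1 had 0 and 99, at least 13.0-fold higher. In the other direction, the secreted phospholipase Pla2g2f had 251 counts in B6 and 0 in D2, at least 23.2-fold lower, and the clone transcript 6820402A03Rik had 561 and 0, at least 51.5-fold lower. The immunoglobulin constant gene Ighg2c had 83 counts in B6 and 0 in D2, at least 7.4-fold lower. The effect of D2 variants on alignment to the B6-derived reference was not analysed. A count of 0 in D2 may therefore not reflect transcript level, for Ighg2c as for the other genes.

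Genes changed by 2-fold or more were unevenly spread over the genome. They made up 8.64% of the tested genes on chromosome 4, 7.92% on chromosome 14 and 7.66% on chromosome 1, against 2.37% on chromosome 15 and 2.23% on chromosome X. Within windows of 5 Mb, 23 of 104 tested genes changed by 2-fold or more at 40 to 45 Mb of chromosome 4, 20 of 80 at 35 to 40 Mb of chromosome 17, which holds the H2-Q genes, and 10 of 27 at 135 to 140 Mb of chromosome 6, which holds Pde6h.

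Adjacent genes changed together more often than permuted calls did. Both genes changed by 2-fold or more in 191 adjacent pairs, against a mean of 43.5 in permutations (permutation p = 0.0001, the smallest the permutations can give), and 157 of the pairs (82.2%) moved the same way. Overlapping transcripts or shared sequence are unlikely to be the whole source, since 96 pairs remained without such pairs, against 35.4 (permutation p = 0.0001), 67 of them (69.8%) in the same direction. Stretches of the genome that differ between the strains in regulatory sequence may underlie the grouping, which was not tested, and so may D2 reads lost or misplaced against the B6-derived reference. Read-level data could help to separate these.

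The cone genes fell in D2 by unequal amounts. Reads shared with other genes are an unlikely source, with a median of 0.29% of the words of the 10 lower genes shared and a highest of 8.26%. A lower number of cones alone would lower all cone genes alike if only cones held their transcripts, equally over the retina, which was not tested. Their log2 fold changes spanned 1.7 (heterogeneity Q = 1931, 12 degrees of freedom), with Opn1sw at 0.03 and Pde6c at -1.67. A lower number of cones as a part of the fall is not excluded, since the test asks only whether all cone genes fell alike. The rod list also held unequal changes, from -0.245 to 0.878. Strain differences in the expression of single cone genes, and variants that change alignment to the reference, could both contribute and stay open.

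Optc, Ltbp2, Fbln1, Slc26a4, Slc6a13, Cldn2 and Gpx3, chosen after their values were seen, had log2 fold changes of -3.90 to -2.42. Less pigment epithelium in the D2 samples is unlikely to be the source, since that list had a mean log2 fold change of -0.297 ± 0.131 (standard error over its members) against a smallest fall of -2.42 among the 7 genes. Its members varied over the alternatives, Rgr from -1.24 to 0.004, Ttr from -1.61 to -0.51 and Stra6 from -1.22 to -0.55. None of these values reached -2.42. Less ciliary tissue in the D2 samples may be a source: 10 ciliary markers listed before their values were seen had a median of -0.702 ± 0.216, and 9 fell and 0 rose. The most abundant markers, Aqp1 at 114 CPM in B6 and Col9a1 at 67.1 CPM, moved by -0.06 and -0.25, the next, Col18a1 at 58.6 CPM and Fbn1 at 50.1 CPM, by -1.23 and -1.45, and all 10 had counts in every library of both strains. The median lies between the cut-offs chosen here for a loss of tissue and for its absence. Most of these genes and markers fell from D2 replicate 1 to D2 replicate 3, with replicate 2 between. Examples were Fbln1 (8.26, 3.95 and 2.38 CPM) and Fbn1 (21.3, 19.7 and 14.5 CPM). Slc6a13, Col9a2, Col9a3, Otx1 and Aqp1 did not follow that order. Such an order within 1 strain may come from differing amounts of ciliary tissue, which was not tested. Dissection and a strain difference in these genes cannot be told apart.

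The summed counts of the mitochondrial genes and 13 nuclear copies differed by -0.227 ± 0.0494 on the log2 scale between the strains, and the copies alone by -0.26. The log2 fold changes of the 15 mitochondrial genes spanned 0.76.

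Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 5524 or more changed genes and 1 gave 895 or more changed by 2-fold, the strain split in both cases. The highest count of the other splits was 0 by edgeR and by limma-voom and 17 by DESeq2, with 172 to 756 genes at an unadjusted p under 0.05. For the lists, 2 splits gave 9, the strain split included, and the other 8 gave 8, 7, 7, 7, 6, 5, 3 and 1 by camera with the preset correlation. Each of the other splits mixed the strains within its groups, so the strain difference added to the spread within groups. Their counts therefore do not show what would be called without a strain difference. The splits are too few for a share under 0.05.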
